A study of Mus musculus with 14 samples.

How the data were processed

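Histone-mark chromatin immunoprecipitation sequencing was done on mouse neural progenitor cells of an Atrx- and an Atrx+ genotype, both lacking p53, treated with AGK2 at 1 µM or DMSO for 48 h. The labels describe the treatment for the Atrx- cells in their wording for every sample, and genotype and treatment were taken from each sample's title. H3K4me1, H3K27me3 and H4K16ac were analysed in all conditions and H3K27ac in Atrx- cells, giving 14 libraries, 1 per group. Per the submitters' processing notes, the tools were FastQC, Bowtie2 2.4.5 and MACS2 2.2.7.1, and the genome build mm9. Settings of the peak caller, use of an input control, and any filter are not given in the sources used here. Each deposited list has 3 columns, chromosome, start and end, and each list belongs to 1 sample.

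The deposited peak lists hold no score, height, signal or p-value, so peaks were neither ranked nor filtered, and every peak counts equally. In 13 lists each line was a window of 100 bp. In the H3K27ac list of Atrx- cells with AGK2 start and end were equal on all 85305 lines. Over 16413 pairs within 200 bp, the centres of the DMSO windows lay a median of 32 bp after those positions (mean 21.4, standard error 0.788). To the centres of the H3K4me1 windows the median was 2 to 11 bp over the 4 lists. Positions that are centres would give 0 and starts a positive offset. The offsets to H3K4me1 were thus nearer to centres, and that to H3K27ac matched neither. The positions were nevertheless read as starts of 100-bp windows throughout. They were read as centres only in an alternative for the one-sided H3K27ac counts. Coordinates of H3K27ac regions with AGK2 rest on the reading as starts. Read numbers are not part of the lists. Depth is therefore unknown, and a list can be longer because the library was deeper, the enrichment better or the threshold looser.

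The antibody catalogue numbers given for H3K4me1 and H3K27ac are those known for the other mark of the pair. Marks are named here as in the sample titles. The check planned for this, the share of peaks at transcription starts, needs an annotation in mm9 and was not run. The gene table at hand is in GRCm38.p6, another build than mm9, so no gene names were attached to coordinates. For the same reason promoters and the 21 gene lists fixed in advance were not analysed here, and the comparisons are of regions. The design had assumed scores and an annotation.

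Touching windows were merged into regions, and a region counted as shared when at least 1 bp overlapped the other list. Peaks were also joined across gaps of up to 1 kb, and joined regions of at least 5 peaks were counted, a number that grows with list length. The longer list was therefore also thinned at random to the shorter, with 20 draws, after the data were examined. Such thinning breaks up clusters, the more so the greater the difference in length. A low thinned number is therefore partly fixed by the procedure. Joined regions described as found on 1 side alone lay more than 5 kb from the other list. Near means within 1 kb, a distance chosen after the data were examined. The background was 100 circular rotations of a list along each chromosome, or 20 for subsets of regions, between the lowest and highest position in any list. Rotation keeps the spacing of peaks and takes no account of unmappable sequence. Shares carry 95% Wilson intervals, which treat peaks as independent and cover counting error only. Autosome ranges describe the spread along the genome and not between replicates. Overlap code was tested on simulated windows for the 13 comparisons, where 100% of planted shared windows were found and uniform against rotated placement gave ratios from 0.729 to 1.10. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

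The comparisons were AGK2 against DMSO, 7 in all, and Atrx- against Atrx+, 6 in all, within each mark, then the treatment responses of both genotypes and the marks within a condition. Named regions were to be the 5 with the highest score on each side, more than 5 kb from the other list. With no score, the 5 widest joined regions per side were taken in their place, and the text names those or the widest among them. Coordinates are 1-based in mm9. Alternatives set before the data were examined were an overlap of 50% of the shorter region, 5 kb as the sharing distance, joining across 1 kb, and autosomes alone. Added afterwards were thinning the longer list to the length of the shorter with 20 random draws, single positions as centres, mark overlap at 1 kb and 5 kb, peak ratios from joined regions, and, for regions in both genotypes, autosomes alone and joining of touching peaks only.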

Results

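The data were genome-wide maps of histone marks in mouse neural progenitor cells lacking the tumour suppressor p53, grown as an Atrx- and an Atrx+ genotype. ATRX is a chromatin remodeller that helps place histone H3.3 at repetitive DNA. Cells received AGK2, an inhibitor of the deacetylase SIRT2, at 1 µM for 48 h, or the solvent DMSO. Chromatin immunoprecipitation sequencing covered H3K4me1, a mark of enhancers, H3K27ac, a mark of active enhancers and promoters, H3K27me3, the Polycomb mark, and H4K16ac, an acetylation that SIRT2 can remove. H3K27ac was analysed in Atrx- cells alone. There was 1 library per genotype, treatment and mark, 14 in all, so no difference below has a replicate check and no p-value is given. The lists give positions without read numbers, so the depth behind each is unknown, and the percentages carry 95% Wilson intervals that cover counting error only.

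The lists held between 13224 and 203266 peaks. For H3K4me1 they held 34001 peaks in Atrx- cells with DMSO, 127041 in Atrx- cells with AGK2, 84317 in Atrx+ cells with DMSO and 119358 in Atrx+ cells with AGK2. For H3K27me3 the numbers were 203266, 24824, 41026 and 23984 in the same order, and for H4K16ac 13224, 13238, 70776 and 92281. The H3K27ac lists of Atrx- cells held 64735 peaks with DMSO and 85305 with AGK2. Because nearly all peaks were separate 100-bp windows, the covered length followed the peak number, from 1.32 Mb for H4K16ac in Atrx- cells with DMSO to 20.3 Mb for H3K27me3 in the same cells.

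**Figure D1:**
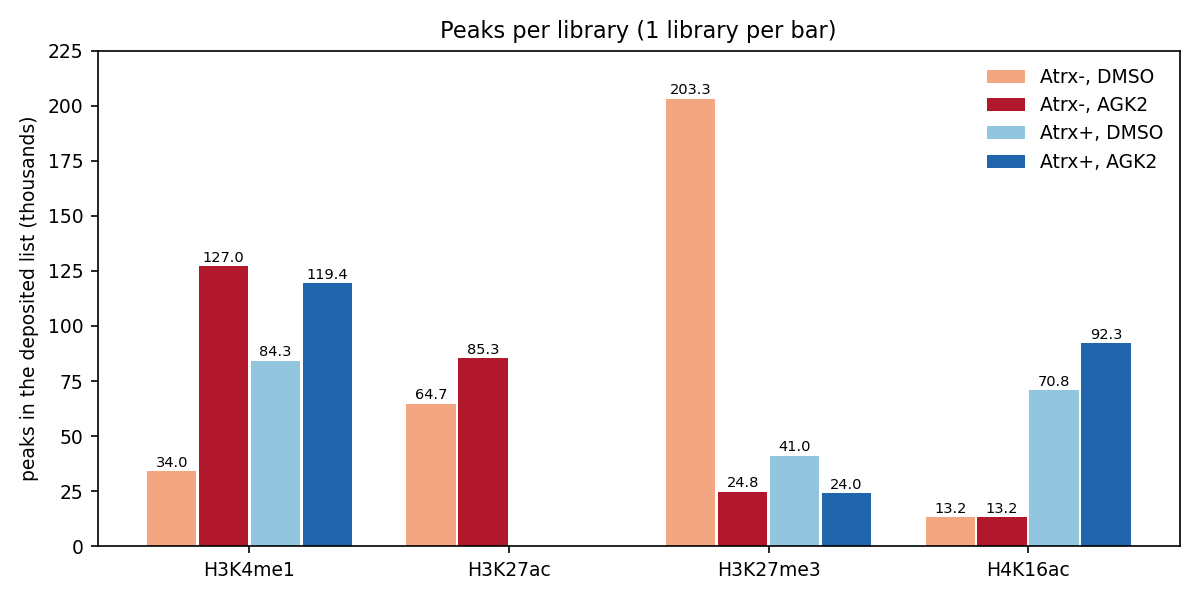
Number of peaks in each deposited list, in units of 1000 peaks, by mark, with colours for genotype and treatment and 1 library per bar, so no error bars. H3K27me3 in Atrx- cells with DMSO had the longest list at 203266 peaks; no H3K27ac list of Atrx+ cells was analysed here.

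The effect of AGK2 on H3K4me1 was compared first in Atrx- cells. Peaks were 3.74 times as many with AGK2 as with DMSO, and the ratio lay between 3.34 and 4.004 on each of the 19 autosomes. H3K4me1 regions of at least 5 neighbouring peaks numbered 1294 with AGK2 and 41 with DMSO. The AGK2 list thinned at random to the DMSO length held a median of 3.5 (0 to 7 over 20 draws). Such thinning breaks up clusters, so thinned numbers here and below cannot show what a shallower library would hold. The widest region marked with AGK2 alone spanned chromosome 3 from 107233834 to 107240256 (mm9), with 10 H3K4me1 peaks with AGK2, none with DMSO in Atrx- cells, and 2 and 4 in Atrx+ cells with DMSO and AGK2. A region on chromosome 19, from 53604940 to 53611090, held 10 H3K4me1 peaks with AGK2, and 5 and 6 in the Atrx+ lists. It also carried 5 H3K27ac peaks with DMSO and 3 with AGK2. The next widest lay on chromosome 6 from 144114419 to 144120103, chromosome 17 from 28169104 to 28174496 and chromosome 14 from 32598937 to 32603951, with 9, 8 and 7 peaks with AGK2. Each of these 5 regions had H3K4me1 peaks in both Atrx+ lists. The widest region marked with DMSO alone, on chromosome 5 from 68180466 to 68182041, held 3 peaks.

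By overlap of at least 1 bp, 121411 H3K4me1 regions of Atrx- cells were in the AGK2 list alone and 28388 in the DMSO list alone. Single-window overlap was rare even between lists marking the same neighbourhoods: 16.5% of DMSO peaks (interval 16.1 to 16.9) overlapped an AGK2 peak, against 66.8% (66.3 to 67.3) within 1 kb. Rotating the AGK2 list along each chromosome gave 1.04% and 8.27%. With a distance of more than 5 kb required, 71088 regions remained with AGK2 alone and 8319 with DMSO alone. After joining peaks within 1 kb, the AGK2-only regions more than 5 kb from any DMSO peak numbered 50825. Of these, 41.1% (40.7 to 41.6) lay within 1 kb of an H3K4me1 peak of untreated Atrx+ cells, against 6.26% for rotated lists, and 27.8% (27.4 to 28.2) lay within 1 kb of an H3K27ac peak of Atrx- cells with DMSO, against 4.58%. The 8217 joined regions found with DMSO alone stood near Atrx+ DMSO H3K4me1 peaks in 6.28% of cases (5.78 to 6.83), against 5.81% for rotated lists.

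In Atrx+ cells H3K4me1 peaks were 1.42 times as many with AGK2 as with DMSO, with 1.33 to 1.52 over the autosomes. Regions of at least 5 peaks numbered 676 with AGK2 and 618 with DMSO, and 155 (141 to 164) in the AGK2 list thinned to the DMSO length. The widest regions marked with AGK2 alone lay on chromosome 15 from 84558835 to 84562782, with 6 H3K4me1 peaks, and on chromosome 8 from 77735586 to 77739286, with 8. Both also held H3K4me1 peaks in Atrx- cells, 1 and 2 with DMSO and 2 and 3 with AGK2. The widest with DMSO alone, on chromosome 7 from 150478015 to 150479993, held 3 peaks. By overlap, 101590 regions were in the AGK2 list alone and 66551 in the DMSO list alone, which became 28554 and 10175 at more than 5 kb. Within 1 kb, 79.5% of the DMSO peaks (79.2 to 79.8) had an AGK2 peak, against 8.16% for rotated lists. Of the 50825 joined regions marked with AGK2 alone in Atrx- cells, 7588 were near one of the 23773 marked with AGK2 alone in Atrx+ cells, 14.9% against 2.37% for rotated regions. The treatment ratios of the genotypes were not tested against each other.

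**Figure D2:**
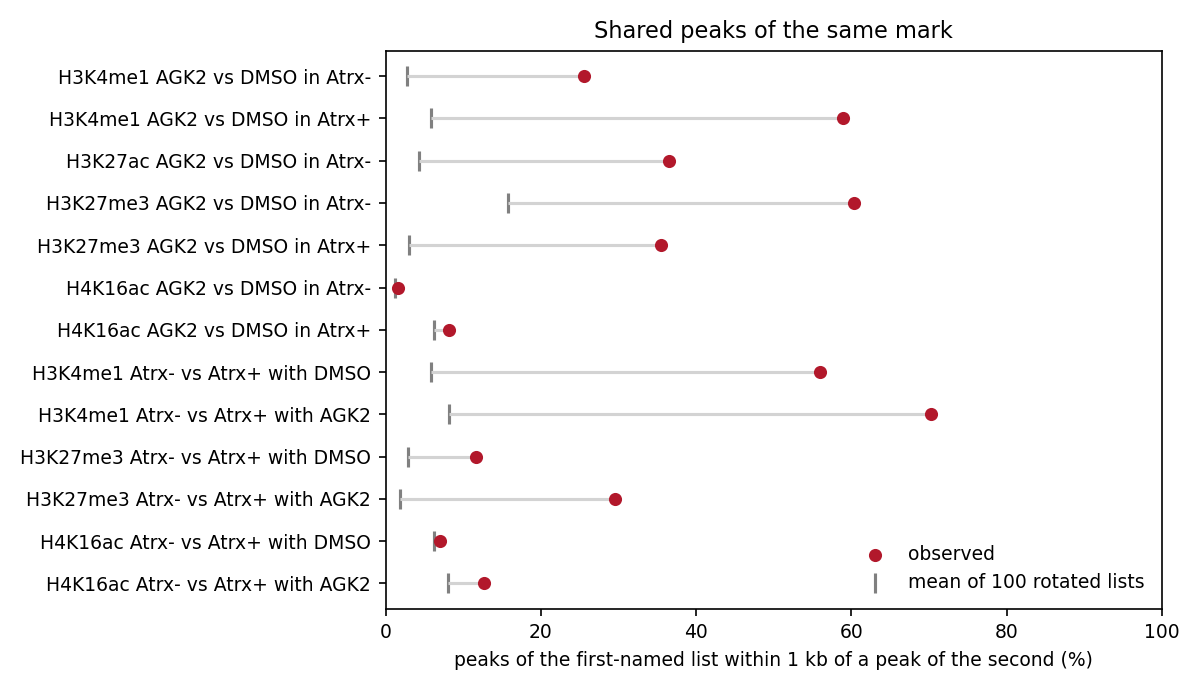
Percentage of peaks of the first-named list within 1 kb of a peak of the second, for the 13 comparisons within a mark; red points are observed values, grey ticks the mean of 100 rotated lists, and each list is 1 library. H3K4me1 lists share far more than rotated lists, up to 70.3% against 8.14%, while the H4K16ac points lie close to their ticks.

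H3K27ac was compared between AGK2 and DMSO in Atrx- cells. The AGK2 list held 1.32 times as many peaks (1.09 to 1.63 over the autosomes), yet fewer regions of at least 5 H3K27ac peaks, 280 against 635, and 85 (73 to 102) when thinned to the DMSO length. The widest region acetylated with DMSO alone spanned chromosome 9 from 35137894 to 35143200, with 10 H3K27ac peaks, and it held H3K4me1 peaks in all 4 H3K4me1 lists. With DMSO it also held 4 H3K27me3 peaks in Atrx- cells and 5 in Atrx+ cells. A second on chromosome 9, from 25291300 to 25295715, held 8, as did chromosome 5 from 93562795 to 93567062. The widest region acetylated with AGK2 alone, on chromosome 5 from 15877075 to 15879165, held 3. In joined regions more than 5 kb from the other list, H3K4me1 separated the sides. Of the 13477 found with DMSO alone, 50.6% (49.7 to 51.4) lay within 1 kb of an H3K4me1 peak of Atrx- cells with AGK2, against 8.56% for rotated lists. Of the 44847 found with AGK2 alone, 7.64% (7.40 to 7.89) did, against 8.19%. Regions of the AGK2 list within 5 kb of a DMSO peak reached 65.0%.

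By overlap, 74837 H3K27ac regions were in the AGK2 list alone and 54265 in the DMSO list alone, or 46162 and 16733 at more than 5 kb. Within 1 kb, 36.5% of AGK2 peaks (36.2 to 36.8) and 52.8% of DMSO peaks (52.4 to 53.2) had a counterpart, against 4.27% and 6.69% for rotated lists. The AGK2 list differed in form from the other 13, giving single positions in place of 100-bp windows on all 85305 lines, so a difference in how the lists were made goes together with the treatment.

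**Figure D3:**
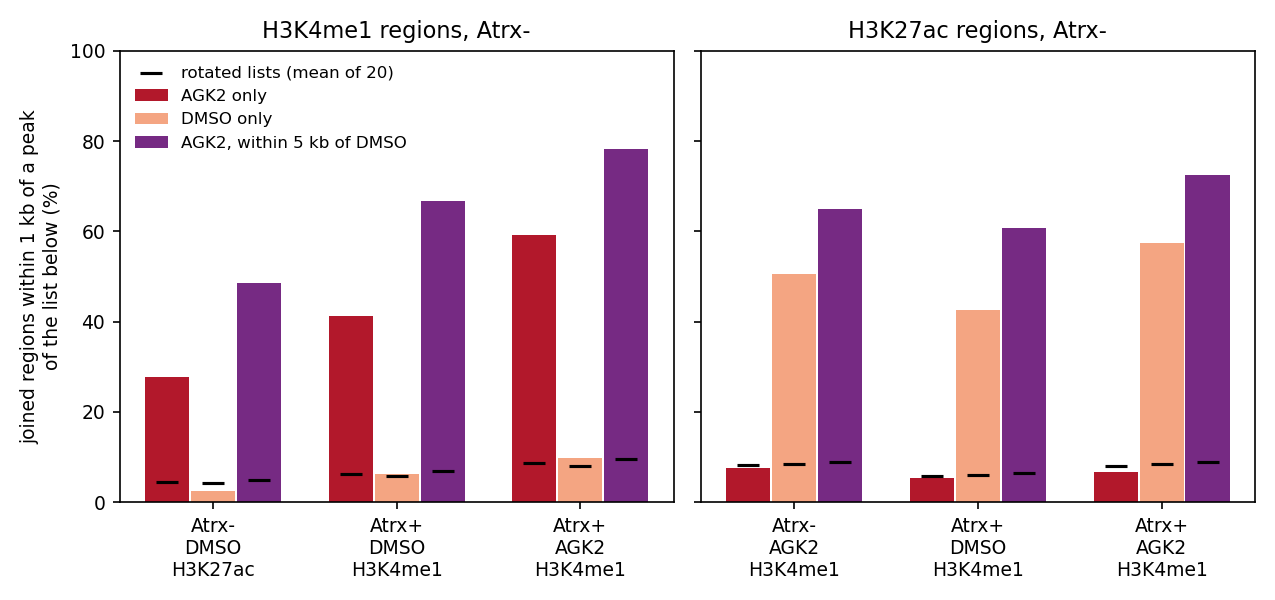
Percentage of joined H3K4me1 regions (left) and H3K27ac regions (right) of Atrx- cells within 1 kb of a peak of the list named below each group of bars, for regions found with AGK2 alone, with DMSO alone, and in the AGK2 list within 5 kb of a DMSO peak; black ticks are means of 20 rotated lists. H3K27ac regions found with AGK2 alone lie near H3K4me1 of the same cells in 7.64% of cases, and those found with DMSO alone in 50.6%.

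For H3K27me3, AGK2 went with a far shorter list in Atrx- cells, 24824 peaks against 203266, a ratio of 0.122 (0.0962 to 0.148 over the autosomes). Regions of at least 5 H3K27me3 peaks numbered 311 with AGK2 and 1226 with DMSO, and 0 (0 to 1) in the DMSO list thinned to the AGK2 length. The widest with DMSO alone lay on chromosome 2 from 104688494 to 104694651, with 9 peaks, and chromosome 8 from 86395746 to 86401535, with 8. Neither held an H3K27me3 peak in Atrx+ cells. The widest with AGK2 alone lay on chromosome 15 from 35233990 to 35236367 and from 102853351 to 102855642, with 4 peaks each, and the second also held 4 in Atrx+ cells with AGK2. By overlap 22028 regions were in the AGK2 list alone and 200461 in the DMSO list alone. At more than 5 kb these were 3801 and 163414. Within 1 kb, 60.3% of AGK2 peaks (59.7 to 60.9) had a DMSO peak, against 15.7% for rotated lists. The 145137 joined regions found with DMSO alone lay near an H3K27me3 peak of untreated Atrx+ cells in 4.35% of cases (4.24 to 4.45), against 2.94% for rotated lists, and the 24358 DMSO regions within 5 kb of an AGK2 peak did so in 33.9% (33.3 to 34.5), against 3.35%.

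In Atrx+ cells H3K27me3 peaks with AGK2 were 0.585 times those with DMSO (0.494 to 0.684 over the autosomes), and regions of at least 5 peaks numbered 279 against 639, or 82 (73 to 96) in the DMSO list thinned to the AGK2 length. The widest region with DMSO alone spanned chromosome 6 from 3891734 to 3898543 and held 13 peaks. The others lay on chromosome 12 from 58381969 to 58387632, chromosome 6 from 82937997 to 82943645, and chromosome 9 from 63232382 to 63238020 and from 63311911 to 63317408, with 9, 9, 9 and 7 peaks. In the order given, these 5 regions held 1, 1, 6, 6 and 3 H3K27me3 peaks in Atrx- cells with DMSO. In Atrx- cells with AGK2 they held 1, 0, 1, 4 and 3. Among the 5 widest with AGK2 alone, 2 lay close together on chromosome 15, from 102832731 to 102835389 and from 102863266 to 102868108, with 4 and 7 peaks. A further 2 lay close together on chromosome 2, from 74520995 to 74523845 and from 74532057 to 74535072, with 5 and 4. By overlap 22376 regions were in the AGK2 list alone and 39414 in the DMSO list alone, or 11247 and 22478 at more than 5 kb. Within 1 kb, 35.4% of AGK2 peaks (34.8 to 36.0) had a DMSO peak, against 3.03% for rotated lists. Of the 145137 joined H3K27me3 regions found with DMSO alone in Atrx- cells, 4587 were near one of the 19644 found with DMSO alone in Atrx+ cells, 3.16% against 1.86% for rotated regions. For regions with AGK2 alone the overlap was 67 of 3728, 1.80% against 0.986%.

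H4K16ac peaks were equally many with AGK2 and DMSO in Atrx- cells, with a ratio of 1.00 that lay above 1 on 10 of the 19 autosomes, and 1.30 times as many with AGK2 in Atrx+ cells (1.10 to 1.45). No H4K16ac list held a region of at least 5 peaks. Between 91.2% and 98.2% of the peaks of each list had no other peak of it within 1 kb. How far list length follows the amount of H4K16ac was not tested. The widest with AGK2 alone in Atrx+ cells lay on chromosome 4 from 58899308 to 58901676 and chromosome 17 from 77019379 to 77021648, with 4 peaks each. The widest with DMSO alone in Atrx- cells, on chromosome 7 from 132294515 to 132296153, held 3. Few H4K16ac sites recurred. In Atrx- cells 13202 regions were in the AGK2 list alone, 13188 in the DMSO list alone and 36 in both, and in Atrx+ cells 91512, 70007 and 768. Within 1 kb, 1.58% of AGK2 peaks of Atrx- cells (1.38 to 1.81) had a DMSO peak, against 1.19% for rotated lists, and 8.17% (7.996 to 8.35) in Atrx+ cells, against 6.19%. The H4K16ac regions with AGK2 alone in Atrx- cells coincided with those of Atrx+ cells in 1005 of 12319 cases, 8.16% against 5.63% for rotated regions, and those with DMSO alone in 555 of 12297, 4.51% against 3.91%.

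The genotypes were then compared within each treatment. Untreated Atrx- cells had 0.403 times the H3K4me1 peaks of untreated Atrx+ cells (0.367 to 0.486 over the autosomes), and 41 regions of at least 5 peaks against 618, or 9 (6 to 17) in the Atrx+ list thinned to the Atrx- length. With AGK2 the ratio was 1.06 (0.966 to 1.22, above 1 on 15 of the 19 autosomes), and such regions numbered 1294 against 676, or 1006 (983 to 1026) in the Atrx- list thinned to the Atrx+ length. The widest H3K4me1 region found in Atrx+ cells alone with DMSO, on chromosome 8 from 129106751 to 129112513, held 9 peaks there and 5 in Atrx- cells with AGK2. The other 4 widest of that kind, on chromosomes 3, 17, 11 and 19, likewise held 2 to 5 H3K4me1 peaks in Atrx- cells with AGK2. Of the 36055 such joined regions, 57.1% (56.6 to 57.6) were near an H3K4me1 peak of Atrx- cells with AGK2, against 8.54% for rotated lists. With AGK2, the widest found in Atrx- cells alone was on chromosome 12 from 71393424 to 71397101 with 7 peaks, and in Atrx+ cells alone on chromosome 1 from 155577068 to 155580990 with 6. By overlap, with DMSO 29520 regions were in Atrx- cells alone and 79828 in Atrx+ cells alone, and with AGK2 106362 and 98673. At more than 5 kb the AGK2 numbers were 19992 and 19812. With peaks within 1 kb joined, the AGK2 ratio turned to 0.986.

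H3K27me3 peaks were 4.96 times as many in Atrx- as in Atrx+ cells with DMSO (3.91 to 6.42 over the autosomes) and 1.04 times with AGK2 (0.811 to 1.18). The widest H3K27me3 region in untreated Atrx+ cells alone spanned chromosome 3 from 127349786 to 127356492, with 13 peaks there and 4 in Atrx+ cells with AGK2. With AGK2, the widest in Atrx- cells alone lay on chromosome 6 from 52101305 to 52108008 and from 51796930 to 51802964, with 10 peaks each and 4 and 7 H3K4me1 peaks of the same cells. In Atrx+ cells alone they lay on chromosome 12 from 50489990 to 50495880 and from 50477610 to 50481595, with 10 and 6 peaks. By overlap, with DMSO 199508 regions were in Atrx- cells alone and 37276 in Atrx+ cells alone, and with AGK2 23486 and 22646. Within 1 kb, 29.5% of the AGK2 peaks of Atrx- cells (28.9 to 30.1) had one in Atrx+ cells, against 1.86% for rotated lists, and with DMSO 11.6% (11.4 to 11.7) against 2.91%. The DMSO lists differ greatly in length. Counted from the shorter Atrx+ list with DMSO, 52.2% (51.7 to 52.7) had an Atrx- peak, against 15.7% for rotated lists. With peaks within 1 kb joined, the AGK2 ratio turned to 0.964.

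H4K16ac peaks in Atrx- cells were 0.187 times those in Atrx+ cells with DMSO (0.138 to 0.255 over the autosomes) and 0.144 times with AGK2 (0.123 to 0.167). The widest H4K16ac regions of Atrx+ cells alone lay on chromosome 14 from 46225637 to 46227796 with DMSO and chromosome 4 from 59713260 to 59716198 with AGK2, with 4 peaks each. By overlap, with DMSO 13125 regions were in Atrx- cells alone and 70676 in Atrx+ cells alone, and with AGK2 13062 and 92104. Within 1 kb, 7.06% (6.63 to 7.50) of the Atrx- peaks with DMSO and 12.6% (12.1 to 13.2) with AGK2 had an Atrx+ peak, against 6.16% and 8.03% for rotated lists.

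Within each condition, the marks were set against each other by overlap of at least 1 bp, as a ratio to rotated lists. H3K4me1 peaks of Atrx- cells overlapped H3K27ac peaks 12.1 times as often as rotated lists with DMSO, in 6.44% of cases (6.19 to 6.71), and 5.08 times as often with AGK2, in 3.55% (3.44 to 3.65). H3K27ac peaks overlapped H3K27me3 peaks less often than rotated lists did, by a ratio of 0.359 with DMSO and 0.484 with AGK2. These AGK2 values rest on the single H3K27ac positions read as window starts, and centres were not tried for overlaps between marks. Within 1 kb, H3K4me1 near H3K27ac gave 8.79 with DMSO and 4.03 with AGK2. The H3K4me1 lists also differed in length, at 34001 and 127041 peaks. H3K27me3 peaks overlapped H3K4me1 peaks by ratios of 0.683 and 1.17 in Atrx- cells with DMSO and AGK2, and 1.05 and 1.52 in Atrx+ cells, where 1.17 and 1.05 lay within the range of the rotated lists. H4K16ac peaks overlapped H3K4me1 peaks by ratios of 0.633 and 0.374 in Atrx- cells with DMSO and AGK2, and 0.501 and 0.492 in Atrx+ cells, where 0.633 lay within that range. With DMSO in Atrx- cells, H4K16ac peaks overlapped H3K27me3 peaks 2.11 times as often as rotated lists. With AGK2 in these cells the ratio was 0.769, within that range, and in Atrx+ cells it was 1.13 with DMSO and 1.09, within that range, with AGK2. The overlap of H3K4me1 with H3K27me3 in AGK2-treated cells, 1.19 in Atrx- and 1.54 in Atrx+ cells, turned to 0.785 and 0.845 when a distance of 5 kb was allowed. Counted from the H3K27me3 peaks, the same setting gave 1.20 and 1.34.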

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

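All tests in this part were chosen after the results were seen. For H3K4me1 the contrast between genotypes went opposite ways in the treatments by some measures. The ratio of peak numbers, Atrx- over Atrx+, was 0.403 with DMSO and 1.06 with AGK2 (above 1 on 15 of the 19 autosomes), and for regions of at least 5 peaks 0.0663 and 1.91. With the longer list thinned at random, Atrx- and Atrx+ cells held 41 and a median of 9 such regions with DMSO. With AGK2 they held a median of 1006 and 676. Random thinning breaks up clusters, so the fall from 618 to 9 follows largely from the procedure. It cannot show whether the contrast depended on list length. By joined regions the contrast went the same way in both treatments, at 0.492 and 0.986. For H3K27me3 the ratio of joined regions changed sides, from 5.54 with DMSO to 0.964 with AGK2. Its peak numbers, at 4.96 and 1.04, did not, nor did its regions of at least 5 peaks, at 1.92 and 1.12. For the last pair, the thinned Atrx- lists held medians of 1 and 278 such regions, against 639 and 279 in Atrx+ cells. The 1 follows largely from the random thinning, so it cannot show whether the pair depended on list length. With 1 library per group the difference between treatments was not tested for either mark.

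The excess of H3K4me1 peaks with AGK2 in Atrx- cells was weighed against 3 explanations. Placement only at sites that lack H3K4me1 in untreated Atrx+ cells is argued against, because the AGK2-only regions lay near Atrx+ DMSO peaks 6.57 times as often as with rotated lists, although 41.1% near such peaks leaves most regions outside it. Exchanged names of the Atrx- DMSO lists of H3K4me1 and H3K27ac are argued against by overlap too: each overlapped the AGK2 list of its own name more, and the product of same-name over cross-name ratios was 5.55, which leaves an exchange in both treatments open. Spearman correlations over 1-Mb bins were mixed. The DMSO H3K27ac list gave 0.909 with AGK2 H3K4me1 and 0.853 with AGK2 H3K27ac. The DMSO H3K4me1 list gave 0.880 with AGK2 H3K4me1 and 0.736 with AGK2 H3K27ac. With the H3K4me1 lists of Atrx+ cells with DMSO and AGK2, the DMSO H3K27ac list gave 0.944 and 0.955. The DMSO H3K4me1 list gave less, 0.849 and 0.8195, as exchanged names would. The AGK2 lists went the other way, with 0.944 and 0.941 for H3K4me1 and 0.838 and 0.817 for H3K27ac. The correlations therefore do not decide whether the DMSO names were exchanged. A lower sensitivity of the Atrx- DMSO H3K4me1 list may account for the excess of peaks, since the same ratio of 6.57 is what missed sites would give. A loss of H3K4me1 without ATRX that AGK2 reverses would give the same overlap and stays open, untested.

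The long H3K27me3 list of untreated Atrx- cells was weighed next. Regions of at least 5 peaks numbered 0.254 times as many with AGK2, but held 7.73% of the AGK2 peaks and 3.70% of the DMSO peaks. A change in isolated peaks alone would have left such regions about as numerous, and there were 311 with AGK2 against 1226 with DMSO. The DMSO list thinned to the AGK2 length held a median of 0. Random thinning breaks up clusters, so the 0 decides nothing. With 1 library per group, a change in isolated peaks alone and a change in clustered ones were not told apart. Isolated peaks of the DMSO list lay near an Atrx+ DMSO peak in 5.93% of cases (5.81 to 6.05), or 2.05 times the rotated level, while those of the AGK2 list reached 8.11 times and DMSO regions of at least 5 peaks 11.9 times. Background calls among the isolated peaks and H3K27me3 specific to untreated Atrx- cells cannot be told apart by the ratio of 2.05, because both would leave peaks without an Atrx+ counterpart and there is 1 library.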

How the results depend on the processing

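The thinning, the single positions as centres, the mark overlaps at other distances, the peak ratios from joined regions and the alternatives for regions in both genotypes were chosen after the data were seen. Overlap of 50% of the shorter region and autosomes alone left all 26 counts of one-sided regions within 1.5 times, as did centred positions for both H3K27ac counts. For the overlap and autosome settings this holds by construction. Most regions of each list were one-sided already. For H3K4me1 with DMSO alone in Atrx+ cells they were 66551 of 84312, and 50% overlap gave 74879. Chromosome X held at most 1.53% of the peaks of a list. Autosomes alone left the 13 peak ratios and the 13 covered length ratios within their counting intervals. With so few peaks on chromosome X, this too was largely fixed in advance. The covered length ratios repeat the peak ratios, since nearly all peaks were separate 100-bp windows. The 6 counts of regions in both genotypes stayed within 1.5 times under their alternatives. Stricter peaks and the top-scoring peaks of each list, transcription start windows, gene bodies and gene list backgrounds were not run, because the lists hold no score and no annotation in mm9 was used here. Unknown depth limits every comparison of list lengths, and with 1 library per group leaving out a replicate does not apply.

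Allowing 5 kb moved 18 of the 26 one-sided counts by over 1.5 times, downwards by construction. With AGK2 alone and DMSO alone they became 71088 and 8319 for H3K4me1 in Atrx- cells, 28554 and 10175 in Atrx+ cells, 46162 and 16733 for H3K27ac, and 11247 and 22478 for H3K27me3 in Atrx+ cells. Single sides that moved were 3801 for H3K27me3 with AGK2 alone in Atrx- cells and 44616 for H4K16ac with DMSO alone in Atrx+ cells. For Atrx- alone and Atrx+ alone they became 11226 and 45462 for H3K4me1 with DMSO, 19992 and 19812 with AGK2, and 13501 and 13826 for H3K27me3 with AGK2. The H3K27me3 count of Atrx+ alone with DMSO became 7914 and the H4K16ac count of Atrx- alone with AGK2 7801.

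Joining peaks within 1 kb moved 9 counts, which also follows from fewer regions. H3K4me1 gave 74102 with AGK2 alone in Atrx- cells, and 58505 with AGK2 alone and 34198 with DMSO alone in Atrx+ cells. H3K27ac with DMSO alone gave 30403 and H3K27me3 with AGK2 alone in Atrx- cells 14118. Between genotypes, H3K4me1 gave 53160 in Atrx+ alone with DMSO, and 52266 in Atrx- alone and 53147 in Atrx+ alone with AGK2, and H3K27me3 gave 24588 in Atrx+ alone with DMSO. Thinning the longer list moved 7 counts, by construction: 32481 for H3K4me1 with AGK2 alone in Atrx- cells, 24482 and 23046 for H3K27me3 with DMSO alone in Atrx- and Atrx+ cells, 32186 for H3K4me1 in Atrx+ alone with DMSO, 40263 for H3K27me3 in Atrx- alone with DMSO, and 13206 and 13213 for H4K16ac in Atrx+ alone with DMSO and AGK2.

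Joined regions in place of peaks turned 2 ratios, both between genotypes with AGK2: H3K4me1 from 1.06 to 0.986 and H3K27me3 from 1.04 to 0.964. The treatment ratios kept their direction, at 2.82 for H3K4me1 in Atrx- cells, 1.67 for H3K27ac, 0.112 and 0.642 for H3K27me3 in Atrx- and Atrx+ cells and 1.29 for H4K16ac in Atrx+ cells. So did the genotype ratios of 0.492 for H3K4me1, 5.54 for H3K27me3 and 0.191 for H4K16ac with DMSO, and 0.149 for H4K16ac with AGK2. The cause was not tested.

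Among the 36 mark overlaps, given as ratios to rotated lists, allowing 1 kb moved 13 and turned 1, and 5 kb moved 23 and turned 3. Turned means outside the range of the rotated lists on opposite sides. Ratios that crossed 1 numbered 4 and 8, these included. In untreated Atrx- cells, 1 kb and 5 kb gave 8.79 and 3.93 for H3K4me1 near H3K27ac, 8.95 and 4.41 for the reverse, 0.422 and 0.697 for H3K27ac near H3K27me3, 0.466 and 0.745 for the reverse, 1.36 and 1.16 for H3K27me3 near H4K16ac, and 1.35 and 1.12 for the reverse. At 5 kb H3K4me1 near H3K27me3 gave 0.822 and the reverse 0.883. In Atrx- cells with AGK2, 1 kb and 5 kb gave 4.03 and 2.11 for H3K4me1 near H3K27ac and 4.19 and 2.21 for the reverse. H3K27ac near H4K16ac, which had been 1.29, gave 0.967 at 1 kb and turned to 0.896 at 5 kb. Its reverse gave 1.08 and 1.04. H3K4me1 near H3K27me3 turned from 1.19 to 0.865 and 0.785. At 5 kb H3K4me1 near H4K16ac gave 0.525, the reverse 0.638, H3K27ac near H3K27me3 0.677 and the reverse 0.663. In untreated Atrx+ cells H3K27me3 near H4K16ac gave 0.972 and 0.948, and at 5 kb H3K4me1 near H4K16ac gave 0.663, the reverse 0.756 and H3K27me3 near H3K4me1 1.27. In Atrx+ cells with AGK2, H3K4me1 near H3K27me3 gave 1.12 and then turned to 0.845, and H3K27me3 near H4K16ac gave 0.946 and 0.900. There 5 kb gave 0.681 for H3K4me1 near H4K16ac, 0.720 for the reverse and 1.34 for H3K27me3 near H3K4me1. The cause was not tested.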

Other observations

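All tests in this part were chosen after the results were seen. Over 2482 bins of 1 Mb on the autosomes, H4K16ac in untreated Atrx- cells was distributed unlike the other H4K16ac lists. Its peak numbers went with those of every list of the other marks, with Spearman correlations across bins of 0.279 to 0.406 for the 4 H3K4me1 lists, 0.336 and 0.387 for H3K27ac and 0.267 to 0.456 for H3K27me3, above 0 on all 19 autosomes. At short range it did not go with H3K4me1 of the same cells, as 2.28% of its peaks were near one, below the lowest rotated share of 2.397%. The other H4K16ac lists gave -0.166 to -0.424 with H3K4me1. They correlated with each other at 0.550 to 0.652, and with the untreated Atrx- list at -0.102, -0.0199 and -0.188. Bins are not independent replicates, and these values describe single libraries.

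Chromosome X carried few peaks in every list, with a density from 0.00677 times the autosome median for H4K16ac in untreated Atrx- cells to 0.232 times for H3K4me1 in Atrx+ cells with AGK2. H3K27me3 also clustered locally on chromosome 14 in Atrx+ cells with AGK2. They held 7 H3K27me3 peaks between 122866773 and 122870688 and 6 between 122861528 and 122865260, where Atrx- cells with AGK2 held none. That absence follows from how the regions were chosen, as found in Atrx+ cells alone. In the same order, Atrx+ cells with DMSO held 0 and 1 H3K27me3 peaks there, and Atrx- cells with DMSO 1 and 0.

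The H3K27ac regions found with AGK2 alone in Atrx- cells lay near H3K4me1 peaks of the same cells 0.934 times as often as with rotated lists. New acetylation at H3K4me1-marked sites is argued against by that value only as the account of the whole set, since regions found with DMSO alone gave 5.91. It may still hold for some of these regions, because background calls among them would dilute the ratio. The reading also takes the mark names from the titles. The same regions lay near H4K16ac peaks of the same cells 1.60 times as often as with rotated lists, and 1.28 to 1.32 times for the other H4K16ac lists. That excess was not particular to H3K27ac, since near the same list H3K4me1 regions found with DMSO alone gave 1.63 in Atrx- and 1.80 in Atrx+ cells, and H3K27me3 regions found with AGK2 alone in Atrx- cells 1.53. Background calls in the AGK2 list and acetylation at sites without H3K4me1 cannot be told apart by the ratio of 1.60, which lies between the bounds set for either reading, and there is 1 library.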
